A study of Salmo salar with 54 samples.

How the data were processed

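RNA was sequenced from Atlantic salmon (Salmo salar) primary hepatocytes, liver cells isolated from 6 male fish by collagenase perfusion and cultured on 3-dimensional scaffolds. Per the labels, cells of each fish were exposed for 48 h on separate plates to arsenite (AsIII, inorganic trivalent arsenic) at 0.1, 1 and 3 µM or to arsenosugar glycerol (AsSug, an organic arsenic compound with arsenic bound to a ribose) at 5, 10, 50 and 250 µM, each plate with its own control. Both compounds were diluted in medium from a 1 mM stock; its solvent and whether controls received the same volume are not given in the sources used here. This gave 9 groups of 6 libraries, 54 in all, with 1 library per fish and group. Per the submitters' processing notes the tools were HISAT2, featureCounts of the Subread package and DESeq2 1.40.2. The genome build, the annotation, the strand setting and the treatment of reads shared between paralogs are not given in the sources used here.

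The deposited table holds a read signal for 18901 genes in each of the 54 libraries: gene read counts that the authors divided by 1 size factor per library. That unit was tested on the values. Dividing each column by its smallest step returned whole numbers for 100% of the values in every library, within a tolerance of 0.1 reads (largest deviation 0.0931), and every listed gene reached 10 reads in at least 12 libraries. The whole reads recovered this way were used for depth, for counting error and in alternative tests. Total reads per library ran from 8.79 to 24.0 M outside the 250 µM group and from 0.898 to 5.38 M within it. With no molecular identifiers, these reads are not independent molecules. The library names in the file header fall into 3 numbered series: 1 held the AsSug control, 5, 10 and 50 µM libraries, 1 held the AsIII libraries and 1 held the 6 libraries at 250 µM AsSug. The labels' protocols also set the RNA integrity of the 250 µM samples apart from the other 48, and the value for that group is not given in the sources used here.

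Gene names came from a reference table of the assembly Ssal_v3.1, matched by GeneID: 18900 of 18901 identifiers were found, of which 6224 carried a gene symbol and 12676 a locus name only. No coordinates were taken from it. Salmon carry many duplicated genes, so a symbol stands for 1 of several possible copies.

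Values were analysed as log2(value + 1) with limma 3.58.1 (empirical Bayes with a mean trend) in R 4.3.3. Genes with a value of at least 10 in at least 6 libraries of the fit were kept. Fish was a term of every model, since cells of each fish were divided over the groups. Same-fish libraries of different groups correlated more than other-fish pairs, with a median r across genes of 0.234 against -0.0432 (AsIII), 0.364 against -0.0744 (AsSug up to 50 µM) and 0.0963 against -0.0296 (250 µM), after removal of group means. Genes are not independent replicates. Each concentration was compared with the control of its own plates. The 4 AsIII groups shared a fit, as did the AsSug control, 5, 10 and 50 µM groups. The 250 µM group was fitted with its control alone because of its RNA integrity. A linear trend over the rank of the concentration was tested for AsIII and for AsSug up to 50 µM. The plates were compared through their controls, and the compounds through the difference of their effects, each against its own control (3 µM AsIII against 5, 50 and 250 µM AsSug), with fish nested in compound. All tests were two-sided. P values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p below 0.05. Fold changes are log2 with the standard error of the limma fit, and the added 1 mostly shrinks them for genes with few reads. At 250 µM AsSug the size factors were 0.106 to 0.590, so the added 1 stands for less than 1 read. A library without reads of a gene can then enlarge its fall.

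Gene lists were fixed before the data were examined, and members were matched by symbol: NRF2 and oxidative stress response, metal binding and transport, arsenic biotransformation and transport, one-carbon metabolism, heat shock and protein folding, ER stress and ATF4 response, proteasome, DNA damage and apoptosis, cell cycle and DNA replication, sterol synthesis, fatty acid synthesis, fatty acid oxidation, xenobiotic metabolism, hepatocyte function, acute phase and inflammation, interferon response, nuclear oxidative phosphorylation, cytosolic ribosomal proteins, glycolysis and hypoxia, DNA and histone methylation, and markers of endothelial cells, stellate cells and fibroblasts, macrophages and granulocytes, lymphocytes, erythrocytes and cholangiocytes. No mitochondrially encoded gene was measured (0 members). Lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. A repeat used an estimated correlation. Members were also counted over all genes tested and adjusted over the list alone. Genes to name were chosen by a rule fixed in advance: the largest changes among called genes that had a symbol, a mean of at least 1 log2 CPM and the same direction in 6 of 6 fish (10 per direction for 3 µM AsIII and 250 µM AsSug, otherwise 5), up to 4 members per list with the smallest p, and a panel of arsenic and stress genes. Of that panel, hmox1, metallothioneins other than mt2, gclm, txnrd1, hsp70, cyp1a and slc7a11 were not found by symbol and are not analysed here. A few further genes that met the naming rule are not reported here and were left out of the check for fish set apart from the others, but stay in the counts of the lists and of all genes.

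The plan written before the data were examined named edgeR on raw read counts. Because the deposited values are divided by size factors, limma on log2 values became the main test and edgeR 4.0.16 on recovered reads with TMM factors became an alternative chosen after the data were seen. Other alternatives were a model without the fish term, DESeq2 1.42.0 and edgeR with median-ratio factors on recovered reads, scaling to library totals, no filter, a filter of 1 CPM in 6 libraries, leaving out each fish, fits on only the groups compared or on all 5 AsSug groups, and fish with a compound term for the differences between compounds. Added after the data were seen were TMM and median-ratio factors with limma, an added value of 0.5 or 5 in place of 1, thinning of controls to the depth of the 250 µM libraries, and 3 further comparisons (3 against 1 µM AsIII, 50 against 5 µM AsSug, and the mean of 5, 10 and 50 µM AsSug against control).

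The test was tried on simulated reads drawn from the real means and depths, with 50 genes changed at each of several fold sizes. Of the genes changed 1.5-fold, 2-fold and 4-fold, 48%, 88% and 100% were recovered for 3 µM AsIII, 72%, 98% and 100% for 50 µM AsSug, and 2%, 52% and 86% for 250 µM AsSug. False calls numbered 7, 2 and 1 of 18806, 18803 and 18562 genes. Few genes were changed in each simulated fit. At 3 µM AsIII and 250 µM AsSug far more were called, which makes the adjusted threshold less strict. The rates therefore do not give the power of those comparisons.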

Results

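The data describe how hepatocytes of 6 salmon responded over 48 h to an inorganic and an organic form of arsenic, with the transcript levels of 18901 genes in 54 libraries. Each of the 9 groups (AsIII control, 0.1, 1 and 3 µM, and AsSug control, 5, 10, 50 and 250 µM) held 6 libraries, 1 per fish. This gave n = 6 fish per group, over which each group mean and SD was taken. Standard errors of fold changes use the spread shared by all libraries of a fit. Values with a fish left out rest on fewer fish. Depth was 8.79 to 24.0 M reads per library in 8 groups and 0.898 to 5.38 M at 250 µM AsSug, where 207 to 921 genes had no reads against at most 39 in any other library. The 50 most abundant genes took 36.3% ± 1.00 (SD) of the reads in the AsIII controls and 36.0% ± 1.39 in the AsSug controls, against 31.8% ± 1.36 at 1 µM AsIII, 31.2% ± 0.845 at 3 µM AsIII and 25.0% ± 3.75 at 250 µM AsSug. The first principal component (39.4% of the variance) set the 250 µM AsSug libraries apart, and the other (27.6%) set the 1 and 3 µM AsIII libraries apart, while those at 0.1 µM overlapped their controls.

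**Figure D1:**
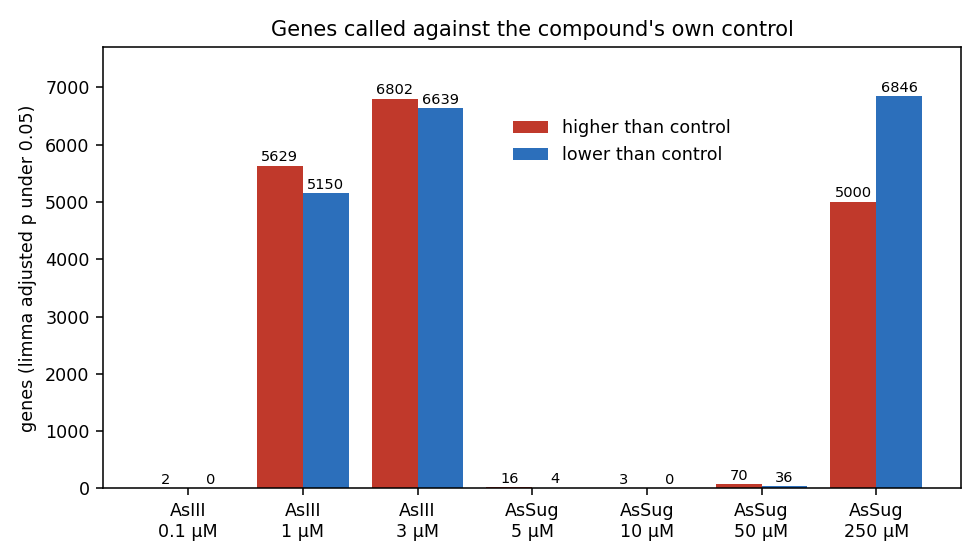
Number of genes called higher (red) or lower (blue) by limma at an adjusted p below 0.05 in each exposure group (x axis) against the control of its own plates, n = 6 fish per group. The counts were 2 and 0 at 0.1 µM AsIII, 5629 and 5150 at 1 µM, 6802 and 6639 at 3 µM, at most 106 in all at 5 to 50 µM AsSug, and 5000 and 6846 at 250 µM AsSug, where scaling to library totals gave 6473 higher and 4933 lower.

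The lowest arsenite concentration, 0.1 µM, was compared with its control to ask whether cells responded to trace inorganic arsenic. gclc (GeneID 100196780), the catalytic subunit of the enzyme that starts glutathione synthesis, rose by 0.45 ± 0.08 on the log2 scale, from 861 ± 102 to 1184 ± 197 normalised reads (SD). zgc:114041 (GeneID 106585395) rose 2.01-fold (standard error 0.16 on the log2 scale). Both rose in 6 of 6 fish (adjusted p = 0.0438 each). No other gene was called. With 46 reads over the 6 control libraries and 89 over the 6 at 0.1 µM, the fold of zgc:114041 rests on few reads. Its standard error came from a spread shared with the 1 and 3 µM groups, which held 885 and 2673 reads. The gene did not reach the filter in the fit of only the groups compared. Among 16 measured genes of the NRF2 and oxidative stress response, 1 rose over all genes tested and 4 when adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.00276; adjusted p = 0.0533 with an estimated correlation). With library totals the median of all genes was -0.11 and that of this list turned to -0.01, still 0.10 above all genes. Cytosolic ribosomal proteins (median 0.13), fatty acid synthesis (0.12), acute phase genes (0.12) and glycolysis (0.08, or -0.03 with library totals) also ranked above other genes (camera adjusted p = 2.7e-07, 0.0119, 0.0133 and 0.0492), with 0 members called in each, over all genes or adjusted over the list alone. None of these passed with adjusted p = 0.481, 0.481, 0.481 and 0.546 with an estimated correlation. The arsenic genes gsto1 (0.33 ± 0.14, adjusted p = 0.626) and as3mt (-0.05 ± 0.11, adjusted p = 0.875) did not pass. Fish differed widely at 0.1 µM in gsto1 (2027 ± 915 normalised reads, SD, against 1514 ± 152 in the control) and mt2 (461 ± 569 against 236 ± 42.8). In ddit3 they did not (369 ± 43.3 against 350 ± 50.4). At an unadjusted p below 0.05, limma gave 1473 of 18899 genes. No gene was called by edgeR, with library totals, with TMM factors, with only the groups compared or without any one of fish 2, 3, 5 and 6, and DESeq2 called 13.

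The next concentration, 1 µM arsenite, was compared with the same control to ask which genes responded to a higher dose. zgc:110339 (GeneID 106573615) rose by 6.11 ± 0.24 and the organic anion exporter abcc3 (GeneID 106589510) by 5.63 ± 0.31, from 5.61 ± 4.38 to 267 ± 59 normalised reads. The sulfotransferase gene chst2 (4.64 ± 0.41), aldehyde oxidase aox5 (GeneID 106574294) (4.58 ± 0.38) and hs90a (GeneID 100380418), an HSP90 chaperone (4.39 ± 0.16), followed. With 14 and 31 reads over the 6 control libraries, the folds of chst2 and aox5 rest on few control reads. Large falls were seen in fam20a (GeneID 106589597), a pseudokinase of the secretory pathway (-4.36 ± 0.21), bhlh3 (-2.70 ± 0.23), the spindle gene aspm (-2.66 ± 0.17), p38a (-2.56 ± 0.26) and the stress-regulated sesn1 (GeneID 106607965) (-2.55 ± 0.16). All of these moved the same way in 6 of 6 fish, and the largest adjusted p among them was 2.4e-08. In all, 10779 of 18899 genes were called (57.0%), 5629 higher and 5150 lower, of which 2432 changed at least 2-fold and 9621 moved the same way in 6 of 6 fish.

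The NRF2 and oxidative stress list rose at 1 µM, with 12 of 16 members higher and 3 lower (the same counts when adjusted over the list alone) and a median of 1.48 (camera adjusted p = 9.2e-05; adjusted p = 0.0107 with an estimated correlation). Examples were gclc (1.85 ± 0.08), the NRF2 repressor keap1a (2.26 ± 0.11) and the autophagy receptor sqstm1 (2.49 ± 0.13). Heat shock genes rose in 7 of 10 members with 1 lower (median 1.74), among them the co-chaperones bag3 (3.67 ± 0.22), dnajb1a (1.92 ± 0.13) and chordc1b (1.82 ± 0.08). Proteasome subunits rose in 9 of 10 (median 0.69), such as psmc6 (0.94 ± 0.08) and psmc5 (0.97 ± 0.16). Of 18 ER stress and ATF4 genes, 10 rose and 4 fell (median 0.40), with the transcription factors ddit3 (1.46 ± 0.08) and atf5a (1.65 ± 0.12) and the glutathione-degrading enzyme chac1 (1.76 ± 0.13) higher. These 3 lists passed camera (adjusted p = 0.00472, 0.00208 and 0.0409, in that order) and had the same counts when adjusted over the list alone, but did not pass with adjusted p = 0.269, 0.375 and 0.364 with an estimated correlation.

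At 1 µM, cell cycle, hepatocyte function, fatty acid oxidation, oxidative phosphorylation and ribosomal protein genes ranked below other genes by camera, and none of the 5 lists kept its call (adjusted p = 0.0773, 0.269, 0.506, 0.364 and 0.559 with an estimated correlation). Cell cycle genes fell in 7 of 13 members and rose in 1 (median -0.66), including the topoisomerase top2a (-2.16 ± 0.16), the proliferation marker mki67 (-1.77 ± 0.21) and the replication helicase subunit mcm6 (-1.12 ± 0.09). Hepatocyte function genes fell in 13 of 19 members and rose in 0 (15 lower when adjusted over the list alone, median -0.40), among them the gluconeogenic enzyme pck1 (GeneID 100195420) (-2.21 ± 0.18), the retinol carrier rbp4 (-1.07 ± 0.11) and apolipoprotein gene apoba (-1.07 ± 0.11). Fatty acid oxidation fell in 11 of 20 and rose in 2 (cpt1b -1.69 ± 0.13, hadhab -0.52 ± 0.11). Oxidative phosphorylation fell in 12 of 26 and rose in 1 (ndufa9a -0.76 ± 0.11). Ribosomal proteins fell in 7 of 42, or in 4 when adjusted over the list alone. Cell cycle, fatty acid oxidation and oxidative phosphorylation kept their counts when adjusted over the list alone. Camera gave these 5 lists adjusted p = 0.0109, 5.5e-05, 0.0262, 0.0109 and 0.0109, in the order named. Among markers of other cell types, stellate timp2 (1.75 ± 0.12) and fn1a (0.66 ± 0.21) and endothelial esamb (0.64 ± 0.09) rose, and macrophage cd68 (-0.45 ± 0.12), cholangiocyte anxa4 (-0.33 ± 0.10) and erythrocyte rhag (-0.42 ± 0.15) fell, with the same calls adjusted over the list alone; the other 7 markers were not called. The call of fn1a was lost without fish 4 and that of rhag without fish 2, 4 or 6. Of the enzymes that process arsenic, the glutathione transferase gsto1 rose by 0.98 ± 0.14 and the arsenite methyltransferase as3mt fell by 0.78 ± 0.11.

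At 3 µM, the highest arsenite concentration, several chaperone genes were among the largest increases. hs90a (GeneID 100380418) went from 1592 ± 553 to 144510 ± 10957 normalised reads (log2 6.56 ± 0.16). bag3 (GeneID 100286445) went from 223 ± 43.6 to 33925 ± 6353 (7.24 ± 0.22). The small heat shock gene hsp30 (GeneID 100195939) rose by 8.13 ± 0.63 and the chaperone dnaja (GeneID 106584850) by 5.07 ± 0.14. Other large increases were in aox5 (8.52 ± 0.38), chst2 (7.18 ± 0.41), odad4 (GeneID 106601019) (6.90 ± 0.18), zgc:114041 (5.99 ± 0.16), csrnp1b (5.95 ± 0.17) and rhov (5.38 ± 0.23). fam20a fell by 4.28 ± 0.21, cyp24a1 (GeneID 106583685), the enzyme that inactivates vitamin D, by 3.21 ± 0.09, and dio3b (GeneID 106608133), the deiodinase that inactivates thyroid hormone, by 3.07 ± 0.17. The neuronal navigator gene nav2b, the transcription factors klf6a and elf3, igdcc4, apolipoprotein E (apoeb), fastkd5 and pck1 fell by 2.69 to 3.05. Each moved the same way in 6 of 6 fish, with adjusted p of at most 2.2e-08. Over all genes, 13441 of 18899 were called (71.1%), 6802 higher and 6639 lower, and 5328 changed at least 2-fold (3180 higher, 2148 lower). Library totals moved the median of all genes from -0.02 to -0.14 and gave 6005 higher and 7705 lower.

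**Figure D2:**
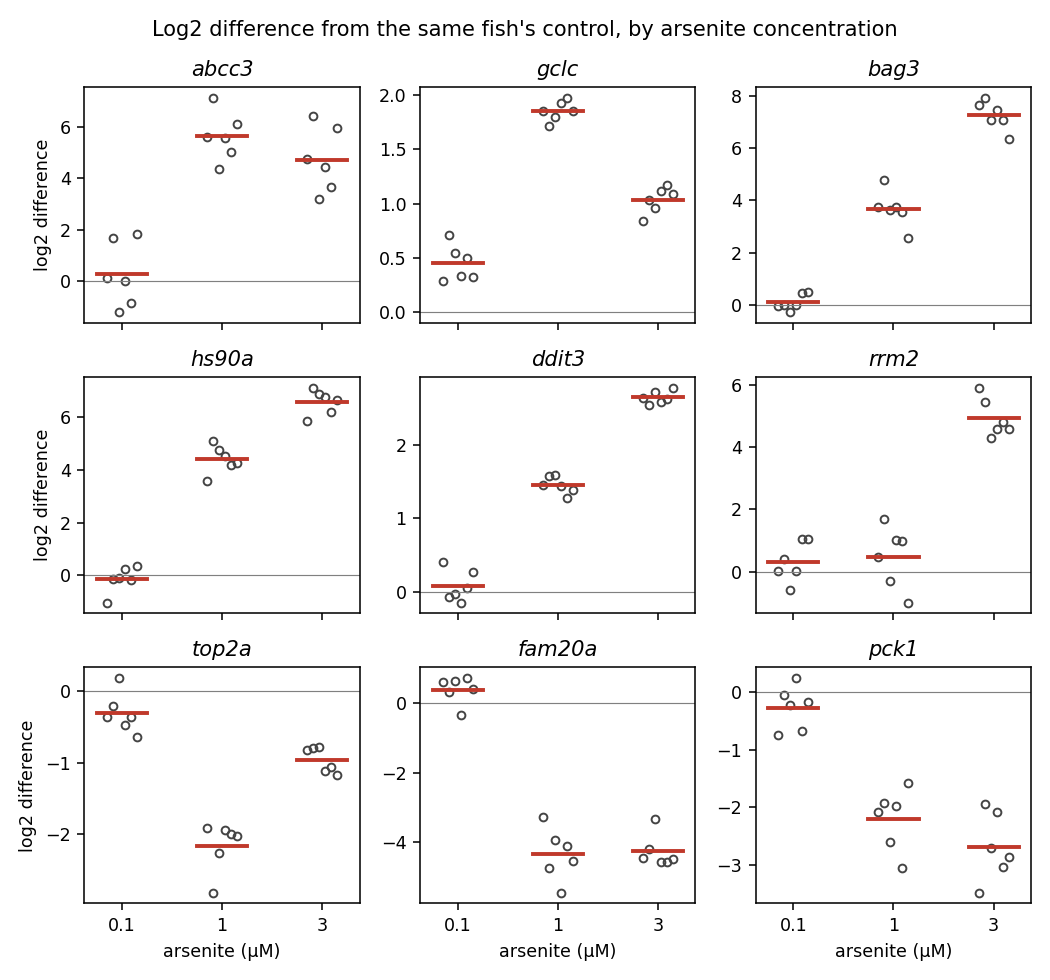
Log2 difference of each exposed library from the control library of the same fish (y axis) at 0.1, 1 and 3 µM arsenite (x axis) for 9 genes. Circles are 6 fish and the red line is their mean; bag3, hs90a and ddit3 were higher at 3 than at 1 µM, gclc and abcc3 lower, and rrm2 stood apart at 3 µM.

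Heat shock and protein folding genes rose in 7 of 10 members at 3 µM and fell in 2, with a median of 2.66 (camera adjusted p = 0.0101; adjusted p = 0.316 with an estimated correlation), including dnajb1a (3.51 ± 0.13), chordc1b (2.76 ± 0.08) and the HSP90 activator ahsa1a (2.56 ± 0.09). ER stress and ATF4 genes rose in 12 of 18 and fell in 1, with a median of 0.90 (adjusted p = 0.0101; adjusted p = 0.259 with an estimated correlation), including ddit3 (2.65 ± 0.08), chac1 (2.71 ± 0.13) and xbp1 (2.10 ± 0.09). NRF2 genes rose in 12 of 16 and fell in 4, with a median of 1.11 (adjusted p = 0.0129; adjusted p = 0.216 with an estimated correlation). Here sqstm1 (3.05 ± 0.13), thioredoxin (txnb, 2.94 ± 0.15) and maff (2.56 ± 0.10) were higher, and the antioxidant srxn1 fell (-0.56 ± 0.18), a call that was lost without fish 3 (adjusted p = 0.0613). Proteasome subunits rose in 9 of 10 and fell in 1, with a median of 0.87 (adjusted p = 0.0129; adjusted p = 0.661 with an estimated correlation), such as psmc5 (1.53 ± 0.16) and psmc6 (1.43 ± 0.08). Hepatocyte function genes fell in 12 of 19 and rose in 1, with a median of -0.34 (adjusted p = 0.0129; adjusted p = 0.661 with an estimated correlation), among them pck1 (-2.69 ± 0.18), apoba (-0.99 ± 0.11) and rbp4 (-0.74 ± 0.11). Counts of these 5 lists were the same when adjusted over the list alone.

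The other lists moved in both directions at 3 µM and did not pass camera, with adjusted p from 0.108 (oxidative phosphorylation) to 0.901 (arsenic biotransformation). In the DNA damage and apoptosis list 10 of 16 genes rose and 5 fell, with plk3 (3.97 ± 0.27), ccng2 (3.29 ± 0.19), btg2 (2.18 ± 0.13) and the cell cycle inhibitor cdkn1a (1.19 ± 0.23) higher and sesn1 (-2.67 ± 0.16) lower. Cell cycle genes were split, 4 higher and 5 lower of 13: the ribonucleotide reductase subunit rrm2 (GeneID 106607664) rose by 4.93 ± 0.31 while top2a fell by 0.96 ± 0.16. Inflammation genes rose in 7 of 14 and fell in 2, including the chemokine il8 (3.50 ± 0.30) and the prostaglandin synthase ptgs2b (3.80 ± 0.36). Interferon genes split 2 to 4 of 9, with isg15 higher (1.83 ± 0.13) and cmpk2 lower (-1.72 ± 0.17). Methylation genes rose in 7 of 10 and fell in 2 (tet1 1.42 ± 0.18, the histone demethylase kdm6ba 1.42 ± 0.18). One-carbon genes rose in 5 of 12 and fell in 4 (mthfd2 2.72 ± 0.13, bhmt -1.48 ± 0.14). Sterol synthesis split 5 to 6 of 15 (insig1 -1.85 ± 0.16), fatty acid synthesis 1 to 4 of 12 (gpam -1.48 ± 0.09), both as higher to lower. On the same footing fatty acid oxidation split 3 to 12 of 20 (cpt1ab 1.92 ± 0.16, cpt1b -1.39 ± 0.13) and oxidative phosphorylation 2 to 12 of 26 (ndufa9a -1.03 ± 0.11). Glycolysis and hypoxia split 1 to 8 of 17 (pdk1 -1.29 ± 0.16), xenobiotic metabolism 2 to 1 of 5 (tiparp 2.04 ± 0.19) and metal binding 1 to 3 of 6 (metallothionein mt2 1.23 ± 0.30, zinc exporter slc30a1a -1.45 ± 0.11). Of 3 arsenic biotransformation genes, gsto1 rose (0.53 ± 0.14) and as3mt fell (-0.67 ± 0.11). Adjusted over the list alone these counts were the same, except 11 lower in oxidative phosphorylation and 0 of 42 ribosomal proteins, of which 1 rose and 4 fell over all genes. Markers of other cell types moved apart within their lists: endothelial esamb rose (2.64-fold) and kdr fell (-1.13 ± 0.33). Stellate timp2 rose (2.39 ± 0.12) and fn1a fell (-1.43 ± 0.21), and macrophage mpeg1.1 rose (1.11 ± 0.21) and cd68 fell (-0.82 ± 0.12). The cholangiocyte marker jag1b rose (1.04 ± 0.13) and the single lymphocyte and erythrocyte markers were not called. The marker lists measured 3, 4, 2, 2, 1 and 1 genes, and every count was the same adjusted over the list alone.

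Responses to 1 and 3 µM arsenite had much in common. Both raised 4656 genes, where 2026 were expected from independent lists, and both lowered 3954 against 1809. Only 188 and 197 genes moved in opposite directions. Across genes the changes correlated (r = 0.796; 0.806 and 0.712 with each concentration set against a different part of the controls), and simulated unchanged groups sharing the controls gave a covariance of 0.0135 against 0.611. At 0.1 and 1 µM, r was 0.0769 with a covariance of 0.0110, no more than shared controls gave (0.0135). At 0.1 and 3 µM, r was 0.0977 with a covariance of 0.0207 against 0.0134 from shared controls, and with the controls divided r was 0.00830 and 0.127.

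Set directly against 1 µM, a comparison added after the values were seen, 3 µM arsenite raised hsp30 by a further 4.97 ± 0.63, rrm2 by 4.46 ± 0.31 and the telomere-binding gene terf1 by 4.34 ± 0.22. It lowered the DNA repair nuclease gene ercc4 by 2.76 ± 0.22 and the growth factor binding protein igfbp-1b1 by 2.60 ± 0.13. Heat shock genes (7 of 10 higher, 0 lower, median 0.92), ER stress genes (10 of 18, 1 lower, 0.38) and cell cycle genes (10 of 13, 1 lower, 0.80) ranked higher at 3 µM (camera adjusted p = 0.00658, 0.0174 and 0.0174; adjusted p = 0.26, 0.26 and 0.12 with an estimated correlation). Adjusted over the list alone, the counts were 7, 10 and 10 higher. In all, 9859 genes differed, 5247 higher and 4612 lower, or 3492 and 6822 with library totals, which moved the median of all genes to -0.16.

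Over the rank of the arsenite concentration, aox5 (3.03 ± 0.26 per step), hsp30 (2.70 ± 0.29), chst2 (2.58 ± 0.20) and bag3 (2.53 ± 0.19) rose most steeply among genes with a symbol, and fam20a (-1.76 ± 0.22) and klf6a (-1.11 ± 0.09) fell most steeply. The trend was called for 12989 genes, 6565 rising and 6424 falling. Heat shock, proteasome, ER stress and NRF2 lists trended up and hepatocyte function and oxidative phosphorylation down (adjusted p = 0.017, 0.00804, 0.0187, 0.037, 0.00804 and 0.037). In that order 7 of 10, 9 of 10, 11 of 18 and 12 of 16 members rose and 13 of 19 and 14 of 26 fell, over all genes and adjusted over the list alone. Each had adjusted p = 0.621 with an estimated correlation.

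The lower arsenosugar concentrations (5, 10 and 50 µM) were compared with their control to ask whether the organic form acted on these cells, and few genes responded. fam20a, which arsenite lowered at 1 and 3 µM but not at 0.1 µM, rose at all 3 concentrations, by 0.73 ± 0.09 (adjusted p = 2.9e-04) at 5 µM, 0.60 ± 0.09 (adjusted p = 0.00344) at 10 µM and 0.69 ± 0.09 (adjusted p = 2.9e-04) at 50 µM, from 280 ± 90.2 normalised reads in the control to 454 ± 98.7, 417 ± 103 and 441 ± 90.0. At 250 µM, in libraries that also differed in depth, series and RNA integrity, its mean was 74.1 ± 39.3, below that control. The kinase gene pim2 (GeneID 100194767) rose by 0.89 ± 0.14 (adjusted p = 0.00208) at 5 µM, and sesn1 fell by 0.37 ± 0.07 (adjusted p = 0.0292) at 5 µM and 0.36 ± 0.07 (adjusted p = 0.0145) at 50 µM. That call was lost without any one of fish 1 to 5 at 5 µM and of fish 2 to 5 at 50 µM, and with library totals (adjusted p = 0.0886 to 0.240 and 0.0625 to 0.107). At 50 µM the mitochondrial glycine carrier slc25a38b (GeneID 106586953) (0.77 ± 0.14, adjusted p = 0.00654), the chromatin regulator bmi1a (0.73 ± 0.15), zgc:92242 (0.66 ± 0.10) and aldh5a1 (0.53 ± 0.12) rose. The taurine transporter slc6a6 (GeneID 100136527) (-0.89 ± 0.14, adjusted p = 0.00219), pptc7a (-0.35 ± 0.07) and sema4gb (-0.30 ± 0.07) fell, all in 6 of 6 fish. Of the calls named here, those of fam20a and pim2 at 5 µM and of fam20a, slc6a6 and zgc:92242 at 50 µM held without any one fish. Called genes numbered 20 at 5 µM (16 higher), 3 at 10 µM (3 higher) and 106 at 50 µM (70 higher, 36 lower) of 18818. Of the 16 genes higher at 5 µM, 14 were also higher at 50 µM (0.0595 expected from independent lists), and all 4 lower genes were shared. Both groups were set against the same controls. With the controls divided between them by fish, no gene was called in both, but each fit then held only part of the fish. Leaving out 1 fish already lowered the counts to as few as 7 and 31. The division therefore cannot tell whether shared controls made the overlap. At 50 µM, ER stress genes ranked above other genes with 0 of 18 members called, over all genes or adjusted over the list alone (median 0.06, camera adjusted p = 0.0126; adjusted p = 0.572 with an estimated correlation). No other list was called at 5, 10 or 50 µM, and the NRF2 list had 0 of 15 members called at each. No gene was called at any of these concentrations in the model without the fish term, and with all 5 AsSug groups in 1 fit the counts were 0, 0 and 4. The counts were 7, 2 and 31 when fish 2 was left out and 38, 15 and 178 when fish 6 was.

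**Figure D3:**
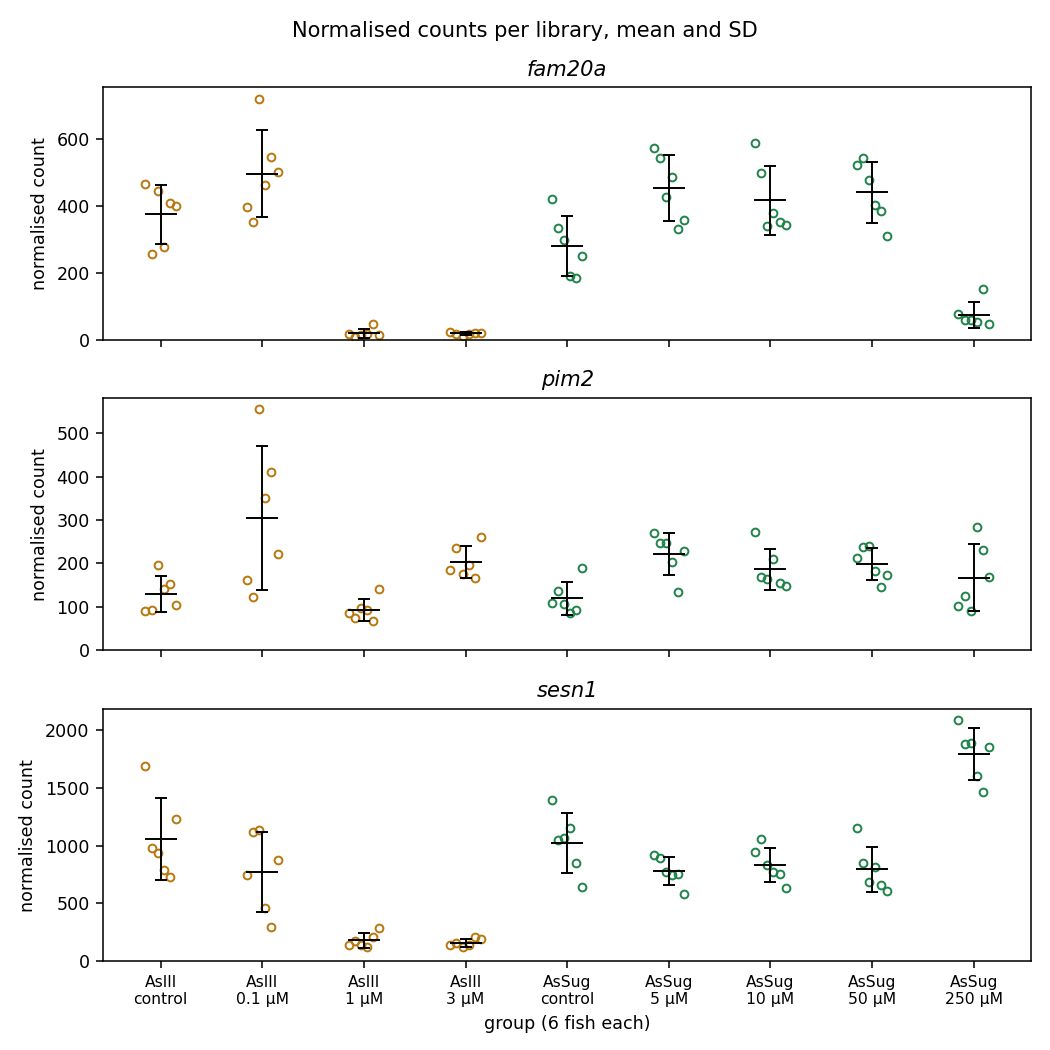
Normalised counts (reads divided by the size factor of the library, y axis) of fam20a, pim2 and sesn1 in the 9 groups (x axis), with a circle for each of 6 fish and bars for the mean and SD. In fam20a the means were 280 in the AsSug control and 454, 417, 441 and 74.1 at 5, 10, 50 and 250 µM AsSug. On the arsenite plates they were 375 in the control and 497, 19.4 and 18.4 at 0.1, 1 and 3 µM arsenite.

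The mean of these 3 arsenosugar groups, a comparison added after the values were seen, differed from the control in 47 genes, 36 higher and 11 lower. Those that moved in 6 of 6 fish included fam20a (0.67 ± 0.08, adjusted p = 1.3e-05), zgc:92242 (0.46 ± 0.10) and foxred1 (0.29 ± 0.06) (higher) and sesn1 (-0.34 ± 0.06, adjusted p = 0.00569) (lower). Without the fish term no gene was called, and without fish 2 or fish 6 the count was 19 or 111. The calls of zgc:92242 (edgeR, DESeq2, or without any one of fish 1 to 4), foxred1 (without any one of fish 2 to 5) and sesn1 (without fish 3 or 4) were lost. Between 50 and 5 µM no gene differed by limma (1037 genes at an unadjusted p below 0.05), while edgeR and limma on only these groups called 1 and DESeq2 3. Over the rank of the concentration up to 50 µM, slc25a38b (0.23 ± 0.05 per step), zgc:92242 (0.19 ± 0.04) and the nuclear exporter xpo1a (0.13 ± 0.03) rose and slc6a6 fell (-0.26 ± 0.05), among 31 genes (20 rising, 11 falling). Each of these 4 calls was lost when certain single fish were left out. ER stress genes again ranked upward with 0 members called (adjusted p = 0.0177; adjusted p = 0.645 with an estimated correlation). The trend count was 0 without the fish term, 75 with DESeq2, 8 without fish 4 and 51 without fish 6.

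At 250 µM arsenosugar, 14 of 15 genes of sterol synthesis fell (a list call with adjusted p = 0.855 with an estimated correlation), as did the gluconeogenic pck1. This was seen in libraries that also had the fewest reads, the lowest share of reads in abundant genes and RNA integrity set apart by the labels, and with the largest share of stock solution in the medium. pck1 went from 1034 ± 286 to 31.6 ± 19.1 normalised reads (log2 -5.11 ± 0.28). nat8l2 (-4.93 ± 0.34), dnajc4 (-4.64 ± 0.53), zmpste24 (-4.54 ± 0.50) and the lipase lipea (-4.08 ± 0.62) were among the other large falls, and these 5 folds rest on 63, 17, 10, 32 and 27 reads over the 6 libraries at 250 µM, in the order named. Among genes with a symbol, pbxip1b (GeneID 106575541) rose most, by 6.70 ± 0.23, followed by the calcium release channel ryr2a (GeneID 106613696) (5.61 ± 0.20), rab11fip1b (4.79 ± 0.20), kirrel3a (4.72 ± 0.86, with fish 2 alone at 11.7), ttyh1 (4.66 ± 0.30) and arap2 (4.56 ± 0.26). Adjusted p was at most 2.1e-04 for these genes, and each moved the same way in 6 of 6 fish. In all, 11846 of 18756 genes were called (63.2%), 5000 higher and 6846 lower, with 7424 changed at least 2-fold.

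Sterol synthesis fell as a group at 250 µM: 14 of 15 genes were lower and 1 higher, with the same counts when adjusted over the list alone and a median of -1.36 (camera adjusted p = 4.8e-04; adjusted p = 0.855 with an estimated correlation). These included the cholesterol synthesis enzymes lss (GeneID 106581851) (-2.16 ± 0.13), mvda (-1.97 ± 0.17) and acat2 (-1.39 ± 0.13). No other list passed camera at 250 µM. Hepatocyte function genes fell in 13 of 19 and rose in 3 (median -1.11, adjusted p = 0.0985), with apoa1 (-1.68 ± 0.21) and transferrin (tfa, -2.03 ± 0.26) lower. Fatty acid oxidation fell in 14 of 20 (adjusted p = 0.14), for example acadvl (-2.79 ± 0.23) and etfa (-1.90 ± 0.17). Fatty acid synthesis fell in 7 of 12 (adjusted p = 0.355), for example the elongase elovl5 (-2.90 ± 0.18) and desaturase fadsd5 (-1.88 ± 0.15). Of 16 NRF2 genes 9 fell and 2 rose (adjusted p = 0.177), with gclc (-1.92 ± 0.16), keap1a (-1.67 ± 0.15) and sqstm1 (-1.73 ± 0.17) lower. Heat shock genes split 3 higher to 5 lower of 10, with hsp90ab1 (-1.42 ± 0.16) and hspa8 (-1.12 ± 0.18) lower and hsf2 (1.59 ± 0.21) higher. The metal-binding gene mt2 (GeneID 100136581) rose by 3.09 ± 0.20, from 201 ± 45.9 to 1760 ± 569 normalised reads. The AP-1 genes junb (GeneID 100194872) and jun rose by 3.95 ± 0.20 and 2.71 ± 0.19. The stress gene ddit3 (0.29 ± 0.18, adjusted p = 0.168) did not pass, though it did with library totals (0.59, adjusted p = 0.00937). Adjusted over the list alone the counts were the same for these lists, except 5 higher in fatty acid oxidation and 4 higher in fatty acid synthesis. Markers of other cell types moved apart at 250 µM. Stellate timp2 (-1.47 ± 0.20) and fn1a (-1.97 ± 0.33) fell, as did timp2a (-1.18 ± 0.46), with 26 reads there, a call lost with library totals, with thinned controls or without any one of fish 3 to 6. Macrophage cd68 fell (-1.51 ± 0.16) while the other macrophage marker, mpeg1.1, was not called. Of 3 endothelial markers esamb rose (0.57 ± 0.16) and kdr, with 14 reads there, fell (-2.28 ± 0.77). Cholangiocyte jag1b rose (2.69 ± 0.24) and anxa4 fell (-0.43 ± 0.13), and the calls of anxa4 (library totals, edgeR with TMM, or without fish 2) and kdr (without fish 4) were lost. The single lymphocyte marker was lower and the single erythrocyte marker higher. Every marker count was the same adjusted over the list alone. Scaling shifted the whole comparison: the median of all genes was -0.20 with the authors' size factors, -0.13 with median-ratio factors, -0.10 with TMM and 0.10 with library totals, the last giving 6473 higher and 4933 lower genes. Relative to that median the sterol list stayed at -1.16 and -1.15 with the authors' factors and library totals.

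**Figure D4:**
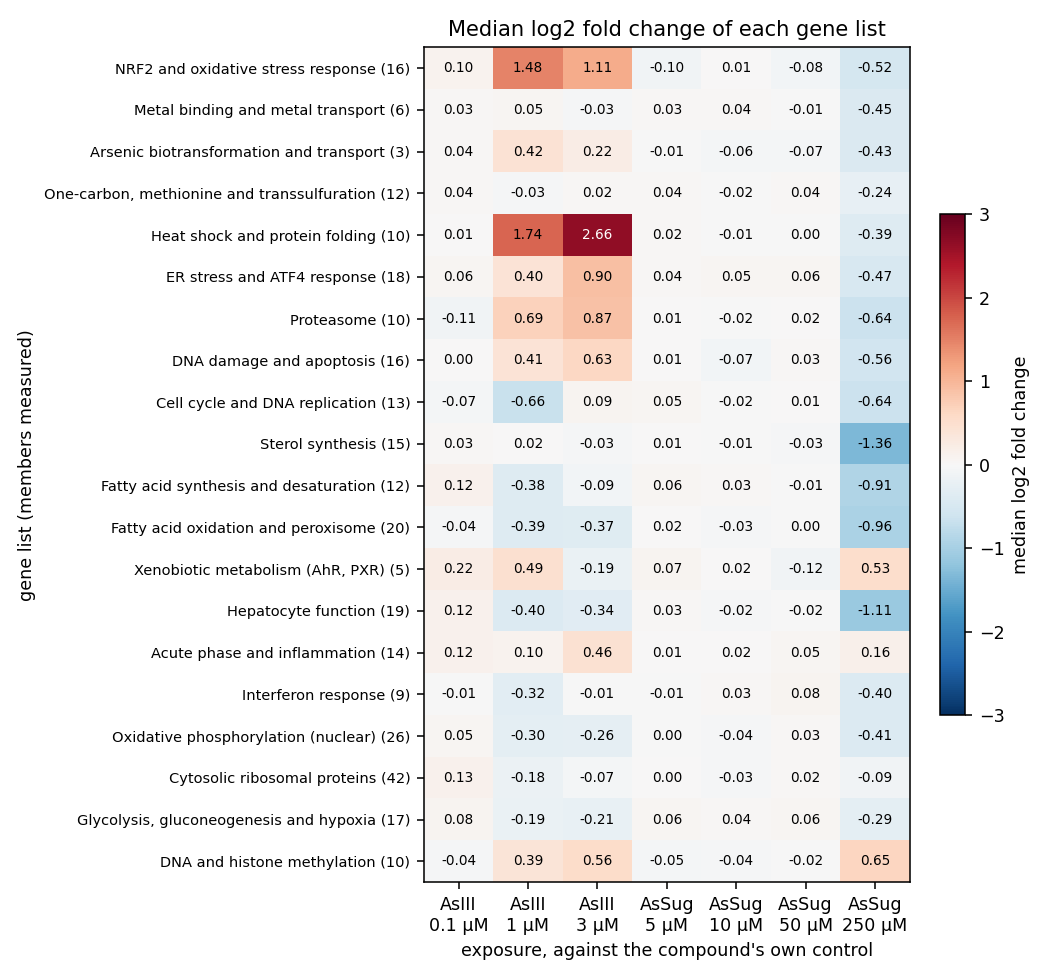
Median log2 fold change (colour and printed value) of each fixed gene list (y axis, with the largest number of members measured) in each exposure group against its own control (x axis), n = 6 fish per group. Heat shock genes reach 2.66 at 3 µM arsenite and sterol synthesis -1.36 at 250 µM arsenosugar. With library totals the medians of one-carbon, ribosomal protein and glycolysis lists at 250 µM, of one-carbon and cell cycle lists at 3 µM, of the one-carbon list at 1 µM, and of 10 lists at 0.1 µM arsenite take the other sign. At 50 µM arsenosugar the heat shock and fatty acid oxidation medians do so with median-ratio or TMM factors.

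The controls of the arsenite and arsenosugar plates, cells without exposure, differed in 11 of 18712 genes, all lower in the arsenite control. The only one with a symbol that met the naming rule was lonrf1 (-0.39 ± 0.07, adjusted p = 0.0328), a call lost without any one fish (adjusted p = 0.0568 to 0.147). Proteasome (median 0.10) and glycolysis genes (0.12) ranked higher and methylation genes (-0.10) lower in the arsenite control (camera adjusted p = 0.00392 each; adjusted p = 0.701, 0.701 and 0.264 with an estimated correlation), with 0 members called, and 0, 0 and 5 lower when adjusted over the list alone. Without the fish term no gene was called, and without fish 3 the count was 3.

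The compounds were compared through the difference of their effects, at the nearest concentrations tested (3 µM arsenite and 5 µM arsenosugar) and at 50 and 250 µM arsenosugar, since no concentration was shared. Against 5 µM arsenosugar, arsenite raised aox5 by 8.05 ± 0.41 more, bag3 by 7.28 ± 0.18, hsp30 by 7.04 ± 0.97 and hs90a by 6.68 ± 0.18. It lowered fam20a by 5.01 ± 0.18, cyp24a1 by 3.21 ± 0.09 and dio3b by 3.13 ± 0.13 more. The effect differed in 13128 of 18898 genes (6569 higher and 6559 lower with arsenite). Lists of heat shock (median difference 2.69), NRF2 (1.19), ER stress (0.91) and proteasome genes (0.86) were higher with arsenite and hepatocyte function lower (-0.29). Camera gave adjusted p from 0.00299 to 0.00751; adjusted p from 0.313 to 0.565 with an estimated correlation. In these lists 7 of 10, 12 of 16, 11 of 18 and 9 of 10 members were higher and 12 of 19 lower, the same when adjusted over the list alone, where 1 proteasome gene was also lower. Against 50 µM arsenosugar, 12973 genes differed (6544 higher, 6429 lower), with aox5 (8.50 ± 0.46), hsp30 (7.77 ± 0.77) and bag3 (7.49 ± 0.19), with fam20a (-4.97 ± 0.18) lower. The same 5 lists were called, with 7 of 10 heat shock and 12 of 16 NRF2 genes higher and 11 of 19 hepatocyte function genes lower, over all genes and adjusted over the list alone. They had adjusted p from 0.00333 to 0.0113, and adjusted p from 0.307 to 0.761 with an estimated correlation. Against 250 µM arsenosugar, 12529 genes differed (7324 higher, 5205 lower, or 5253 and 7116 with library totals). The 250 µM libraries also differed from their controls in depth, series and RNA integrity, so this difference cannot be assigned to the compounds alone. aox5 (8.76 ± 0.57), odad4 (6.82 ± 0.59) and smpd5 (6.47 ± 0.49) were higher with arsenite and klf6a (-5.34 ± 0.25), ryr2a (-5.30 ± 0.32) and the leptin gene lepa (-5.17 ± 0.39) lower, with 12 reads each for aox5 and smpd5 over the 6 libraries at 250 µM and 23 for lepa at 3 µM. With the same counts adjusted over the list alone, sterol synthesis (1.07, 11 of 15 higher), heat shock (3.25, 8 of 10), ER stress (1.47, 14 of 18), NRF2 (1.89, 12 of 16) and proteasome genes (1.19, 8 of 10) were higher with arsenite (adjusted p from 0.00312 to 0.0295; adjusted p from 0.531 to 0.827 with an estimated correlation). The arsenite methyltransferase as3mt was lower with arsenite than with 5 µM arsenosugar (difference -0.70, 95% interval -0.87 to -0.53) and was not shown to differ from 250 µM arsenosugar (-0.23, -0.51 to 0.04, adjusted p = 0.119). srxn1 did not pass there either (-0.13, -0.84 to 0.57). Among genes that did not pass, the 95% interval lay within 1 log2 unit of no difference in 90.4% of 5770 genes against 5 µM, 90.1% of 5925 against 50 µM and 59.2% of 6370 against 250 µM.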

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

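The tests of a difference between library series, of RNA integrity and of the change shared by the lower arsenosugar groups were chosen after their results were seen, as were the direct comparison of 3 with 1 µM arsenite, the genes that rose and fell again by it, and the tests of those genes among the lists and in parts of the fish; the other tests were set before their results were seen.

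At 250 µM arsenosugar 11846 genes were called in 6 libraries that differ from their controls in depth, library series and RNA integrity as well as exposure, and whose medium held the largest share of the 1 mM stock; its solvent and volume in the controls are not given, so an effect of the solvent was not tested. Lower depth is argued against as the whole cause: with the controls thinned to the depth of the same fish's 250 µM library, the lowest of 5 draws kept a share of 0.927 of the count (10979 to 11022 genes). The changes were largely unlike those at 3 µM arsenite, with r = 0.142 across 18754 genes (0.131 to 0.151 without each fish, rho = 0.130) and different controls for the 2 compounds. Changes from series or RNA integrity could also lower this r, so it cannot exclude a response shared with arsenite beneath them. Series and RNA integrity cannot be told apart from the exposure, because no control library is in that series and every sample of the group is affected: the controls of the other 2 series differed in 11 genes, and the 50 genes most abundant in the controls lost reads relative to all genes (median over fish -1.02, from -0.38 to -1.66, lower in 6 of 6 fish; -0.20 at 3 µM arsenite), which degraded RNA or an effect of the exposure may both give. A toxic response to 250 µM arsenosugar, with lower sterol synthesis and higher mt2, therefore stays open beside them.

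The genes called in the mean of the lower arsenosugar groups (47) moved the same way at 0.1 µM arsenite, against its own controls and on other plates, in 45 cases, a share of 0.957 (0.915 to 0.957 without each fish), against 55.5% of all genes. They include fam20a, sesn1 and foxred1; their median change was 0.38 and that at 0.1 µM arsenite 0.27, and 20 of them had an unadjusted p below 0.05 there in the same direction. Growth with concentration stayed undecided: the median change was 0.40, 0.33 and 0.41 at 5, 10 and 50 µM, and the ratio of 50 to 5 µM was 1.04 (bootstrap interval 0.891 to 1.36 over 1000 draws). A candidate explanation is a difference in handling between control and exposed wells that does not depend on compound or concentration; a common response to low arsenic of either form would give the same values and was not separated from it by any test. Also, 35 of the 47 genes lay in that direction in the arsenite control relative to the arsenosugar control, untested as a set. The 47 genes were chosen for a difference from the same arsenosugar control, so such agreement can arise without a real difference between the controls.

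Higher at 1 µM arsenite and lower again at 3 µM than at 1 µM were 1028 genes, of which 303 were still above control at 3 µM, 537 were not called there and 188 were below it; 1067 genes had the mirror pattern. They held 6 of the 12 NRF2 genes that were higher at 1 µM (among them abcc3, gclc and keap1a), against 18.3% of all 5629 genes higher there, and the list did not pass (Fisher's exact test, two-sided, adjusted p = 0.124). Genes chosen in 3 fish lay above the median of all genes at 1 µM and below it from 1 to 3 µM in the other 3 fish. The shares were 0.988 and 0.961, against at most 22.3% of all genes, so their place relative to other genes recurred between fish. The scaling of the libraries, a size factor common to all genes of a library, cancels in that place and cannot make it recur. Whether the scaling set the sign of some of these changes cannot be told from this test. TMM factors, library totals and median-ratio factors kept at least a share of 0.960 of the 1028 genes, which adds little, since none moved the median of all genes against the pattern by more than 0.0145. Depth was not lower at 3 µM (median 12.5 M reads against 11.9 M at 1 µM), and thinning every arsenite library to 8.79 M reads kept a share of 0.864; neither a response that peaks near 1 µM nor loss of the responding cells at 3 µM was tested as a biological explanation.

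The effects of the compounds differed in 13128 genes against 5 µM arsenosugar, 12973 against 50 µM and 12529 against 250 µM, by tests of the difference itself. Of 100 splits of the same libraries, 1 was as large in each case, the real one, and the highest other gave 4532, 4843 and 4582 genes. Against 250 µM the splits cannot tell the compound apart from depth, library series and RNA integrity, in which these libraries also differ from their controls.

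Chance alone sets about 1 in 20 groups of 6 values apart by the gap rule used here (Dixon's 95% value); 17 of 338 sets of gene differences and 3 of 18 sets of library values were, 9 of the gene sets at 250 µM among 103. Among the libraries, fish 1 at 250 µM arsenosugar had 32.0% of its reads in the 50 most abundant genes (others 21.2% to 25.0%), and fish 4 had 21.8 M reads in the arsenite control (others 10.6 to 13.8 M) and 24.0 M at 0.1 µM (others 8.79 to 14.05 M). At 0.1 µM arsenite, as3mt in fish 1 differed from its control by -0.66 (others -0.10 to 0.18). At 1 µM arsenite, atf4 in fish 4 stood at 1.45 (0.88 in the lowest of the others) and cpt1b in fish 1 at -1.03 (-1.94 to -1.70). For 3 µM arsenite the values were -3.36 for fam20a in fish 3 (-4.57 to -4.21), -3.84 for nav2b in fish 4 (-3.07 to -2.63) and 0.21 for tap1 in fish 1 (-0.94 to -0.68). At 5 µM arsenosugar as3mt in fish 3 was at -0.11 (0.03 to 0.09), and between the controls ddit3 in fish 6 was at -0.37 (0.00 to 0.10). At 250 µM arsenosugar fish 2, the library with the fewest reads, was at 11.74 for kirrel3a (2.00 to 4.62), -7.27 for pigo (-4.05 to -2.84), -5.64 for top2a (-1.51 to -0.55; the fitted change was -1.71 and -0.93 without fish 2) and -1.90 for srxn1 (-0.41 to 0.24). Fish 1 was at -2.46 for keap1a (-1.63 to -1.35) and 0.14 for esamb (0.57 to 0.75), fish 3 at -1.09 for slc30a1a (-1.93 to -1.77), and fish 5 at -2.71 for tfa (-1.99 to -1.74) and -4.77 for cd74a (-1.84 to -0.19; the fitted change was -1.59 and -0.95 without fish 5).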

How the results depend on the processing

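The alternatives with TMM or median-ratio factors and limma, edgeR with TMM, another added value and thinned controls were chosen after the data were seen, as were the comparisons of 3 with 1 µM arsenite, 50 with 5 µM arsenosugar and the mean of 3 arsenosugar groups; the others were planned. Counts at 1 and 3 µM arsenite, the arsenite trend, 250 µM arsenosugar, 3 against 1 µM and the differences between compounds stayed within 1.5 times under every alternative run, including leaving out each fish (9575 to 12062 at 1 µM, 12699 to 14084 at 3 µM and 10643 to 11371 at 250 µM), and with controls thinned the 250 µM count was 11021. Shares of higher genes moved by over 10 points with library totals at 250 µM (6473 of 11406 higher), 3 against 1 µM (3492 of 10314), the difference from 250 µM (5253 of 12369), the arsenosugar trend (20 of 23) and the mean of 3 arsenosugar groups (33 of 38). The small counts moved, and the causes were not tested except where fewer libraries or a spread that includes the fish entered by construction. In the model with no replicate block the counts were 1 at 0.1 µM arsenite and 0 at 5, 10 and 50 µM arsenosugar, in the arsenosugar trend, between controls and in the mean of 3 arsenosugar groups, since differences between fish then enter the spread. DESeq2 on recovered reads called 13 at 0.1 µM arsenite, 34 at 5 µM, 14 at 10 µM and 75 in the arsenosugar trend. For 0.1 µM arsenite the count was 0 with edgeR under median-ratio or TMM factors, library totals, TMM factors with limma, an added value of 5, and only the groups compared. For 10 µM arsenosugar library totals gave 11. For 50 µM the fit of only the groups compared gave 34. With all 5 arsenosugar groups in 1 fit, whose spread includes the 250 µM libraries, the counts were 0, 0 and 4 at 5, 10 and 50 µM; for the mean of 3 groups this fit was not run, as it would add the 250 µM group to the mean. Between 50 and 5 µM, edgeR with TMM or median-ratio factors and the fit of only the groups compared called 1 gene and DESeq2 3 in place of 0. Leaving out each fish gave 0 to 8 at 0.1 µM arsenite (0 without fish 2, 3, 5 or 6), 7 to 38 at 5 µM, 2 to 15 at 10 µM and 31 to 178 at 50 µM (lowest without fish 2 and highest without fish 6 each time), 8 (fish 4) to 51 (fish 6) in the arsenosugar trend, 3 (fish 3) to 17 (fish 1) between controls, and 19 (fish 2) to 111 (fish 6) in the mean of 3 groups. Of 410 values of named genes none reversed under any alternative. Calls were lost by 30 without the fish term, 19 with library totals (1 gained), 7 and 4 with edgeR under TMM and median-ratio factors, 2 of 400 with DESeq2, 13 of 135 with all 5 arsenosugar groups in 1 fit (1 gained), and 12, 24, 19, 26, 24 and 15 without fish 1 to 6 in turn. gclc at 0.1 µM arsenite had adjusted p = 0.873 without the fish term, and from 0.0502 to 0.873 over the alternatives that ended its call. Of 352 list tests, 48 lost their call with an estimated correlation, and without the fish term 4 lost and 2 gained one. Matching list members by symbol alone was already the main choice, so it gave the same values and was not run apart. Of simulated 1.5-fold changes, 2% were recovered at 250 µM and 72% at 50 µM arsenosugar, which does not separate depth from the spread between libraries. With few genes changed in the simulation, the share at 250 µM does not give the power of the real comparison, where far more genes were called.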

Other observations

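The splits for 3 against 1 µM arsenite, 50 against 5 µM arsenosugar and the mean of 3 arsenosugar groups were chosen after those results were seen; the others were planned.

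Several genes differed from control in opposite directions at the highest concentrations of the compounds, where at 250 µM the exposure cannot be told apart from library series and RNA integrity (11 genes between the controls of the other 2 series). With 3 µM arsenite gclc was at 1763 ± 209 normalised reads (control 861 ± 102) and with 250 µM arsenosugar at 263 ± 46.2 (control 1007 ± 222). keap1a (1.79 and -1.67), sqstm1 (3.05 and -1.73), xbp1 (2.10 and -0.96), btg2 (2.18 and -1.08) and tnfaip3 (1.30 and -1.13) were higher at 3 µM arsenite and lower at 250 µM arsenosugar, and sesn1 the reverse (-2.67 and 0.84). Higher in both groups were mt2 (1.23 and 3.09), jun (1.82 and 2.71), tiparp (2.04 and 1.16), isg15 (1.83 and 0.72) and jag1b (1.04 and 2.69), and lower in both were pck1, slc30a1a and as3mt (at 250 µM not with library totals, with edgeR and TMM, or without fish 6). The means of hs90a, bag3 and abcc3 in normalised reads also lay above control in both groups, and that of fam20a below it. Over all genes, 2052 were higher with both (1786 expected from independent lists), 2879 lower with both (2418), 2204 higher with arsenite and lower with arsenosugar (2446) and 1386 the reverse (1765).

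At 250 µM, genes of the chromatin list rose in 6 of 10 members, the same count adjusted over the list alone, with tet3 (2.31 ± 0.24) and kmt2a (1.53 ± 0.22) higher and prmt5 (-1.64 ± 0.20) and prmt1 (-1.01 ± 0.18) lower (camera adjusted p = 0.443). Ribosomal protein genes divided into 11 higher, such as rpl14 (1.80 ± 0.16) and rpl36a (1.60 ± 0.16), and 12 lower of 42, or 17 and 8 with library totals. The hypoxia genes ca9 (2.16 ± 0.34) and vegfab were higher and igfbp1a (-2.16 ± 0.26) and the glycolytic enzyme pgam1 (-1.48 ± 0.14) lower.

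Chance was set against each count by 100 splits of the same libraries, the real one among them. For 2 groups or 2 plates, 32 of them exchanged the 2 libraries or plates of some fish and so part the same pairs as the real split, and the others were drawn at random. For the trends and the mean of 3 groups, all 100 exchanged groups within each fish. It can be excluded for 1 µM arsenite (1 split as large, the real one with 10779 genes, highest other 6719) and 3 µM (1, with 13441 and 10028). The same holds for the arsenite trend (1, with 12989 and 1449), 3 against 1 µM (1, with 9859 and 5450) and 250 µM arsenosugar (1, with 11846 and 7122). Splits as large were also a share below 0.05 at 5 µM arsenosugar (3 splits as large, real 20, highest other 132), in the arsenosugar trend (3, real 31, highest other 459) and between controls (3, real 11, highest other 73). No other split of the same pairs was as large at 5 µM and between controls. With many comparisons tested this way and other splits calling several times the real count, chance is less likely there but not excluded. At 10 µM (2 splits as large, real 3, highest other 6) and 50 µM (3, real 106, highest other 186) chance is left open, since 2 of the 32 splits that part the same pairs were as large in each case, a share above 0.05. Chance cannot be excluded at 0.1 µM arsenite, where 8 of the 100 splits called at least 2 genes (highest other 1144), 3 of them among the 32. For 50 against 5 µM arsenosugar the real count was 0, which every one of the 100 splits reaches (highest other 63), so the splits decide nothing. Splits that called several times the real count point to a structure of the samples, which was not tested further: 1144, 132 and 73 genes came from splits that put both libraries of some fish on one side, which the fish term does not match, and 459 from exchanges within fish. Among the 32 splits that part the same pairs, the highest other was 65 at 0.1 µM, 4 at 5 µM, 6 at 10 µM, 133 at 50 µM, 0 at 250 µM and 2 between controls.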
